A study of Mus musculus with 8 samples.

How the data were processed

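The series holds 8 RNA-seq libraries from the small-intestinal mesenchyme of wild-type mice, 4 from E17.5 fetuses and 4 from P14 pups. Per the labels' protocols, intestines were opened and shaken in EDTA to remove the epithelium, RNA was taken from the rest with TRIzol, and libraries were made with an NEBNext Ultra kit. One age label gives the fetal stage as day 17, and the protocol's E17.5 is used here. Groups and replicate numbers came from the sample labels. Nothing in the labels says whether each replicate is a separate animal or a pool, so p-values measure only the spread between these samples, which may be technical.

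The deposited table gives 1 FPKM value per gene and library, with the gene's length, position and biotype. FPKM is reads scaled by gene length and library size, so that genes of different length and libraries of different depth share a scale. CASAVA, fastp, HISAT2, featureCounts, DESeq2 1.20.0 and the genome build GRCm39 are named, per the submitters' processing notes, without saying what each did, and all coordinates here are the table's own, on GRCm39. Which step made the FPKM, and whether counting used strand, is not given in the sources used here. Values of overlapping and antisense genes are therefore uncertain, as are those of genes with near-identical copies, such as Rps2 and its processed copies, the globin genes, the immunoglobulin constant regions, Ccl21a and the hnRNP genes.

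Multiplying each deposited FPKM by the gene's length gave whole multiples of 1 step per library for 100% of values (tolerance 1e-06), which recovers the reads behind each value. They summed to between 16.7e+06 and 19.5e+06 per library. The step also showed that the authors' scaling used an effective library size that was 0.78 times the assigned reads in P14 replicate 1 and 1.02 to 1.06 times in the other 7 libraries. At this depth a gene with no read may still hold up to 3 reads in a library, which covers counting error only. The table lists 46635 loci, of which 302 have no gene name; these took 0.183% to 0.246% of the reads of a library, and 101 of them entered the test.

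Genes with an FPKM of 1 or more in at least 4 of the 8 libraries were tested, 14044 in all, of which 12693 were protein-coding. Values were analysed as log2(FPKM + 1); the pseudocount of 1 makes the fold changes of low genes smaller than their true size. P14 was compared with E17.5 in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with an intensity trend and robust variance moderation, two-sided, and adjusted p-values are limma's with Benjamini-Hochberg adjustment over all tested genes, called under 0.05. Gene lists were compared with all other tested genes by limma's camera with its preset inter-gene correlation of 0.01, adjusted over the 41 lists with at least 5 tested members, and again with a correlation estimated for each list. Fry, which tests each list on its own, was a further alternative. The mean level of the STRIPAK and core spliceosome lists per library was compared by exact permutation tests over the 70 assignments of libraries to ages (35 without P14 replicate 1), with a smallest possible p of 0.0286 in each case.

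The groups, tests, 43 gene lists, rule for named genes and most alternative settings were fixed before the data were examined. Of 1210 list symbols, 1198 matched a gene by name, 11 by a synonym and 1 not at all. The lists cover the STRIPAK complex, the Hippo pathway, YAP and TAZ targets, 5 groups of RNA-processing factors, cell division, the cell types of the gut wall, matrix, signalling, blood, immune and epithelial cells, neighbouring tissues, stress, ribosomes and respiration. Some genes are on more than one list. The rule named Slmap and Stk24; the 12 protein-coding genes with the largest increase and the 12 with the largest decrease among called genes whose ages did not overlap, leaving out predicted models, immunoglobulin and T cell receptor segments and repeated symbols; and, for each list described, up to 3 called members with the largest change plus the tested member with the highest mean level. A list with no called member gave its highest member alone, and some lists are given as counts. The part of the rule on the largest changes was applied to all 8 libraries for the text. It was also applied without P14 replicate 1 and with the epithelial share subtracted, where it names Hmgn2 among the decreases. Hmgn2, Myh11, Acta2, Igf2 and Xist fall outside the rule as used for the text and were chosen after their values were seen.

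The epithelial level of a library is the median, over the tested pan-epithelial markers, of its value relative to P14 replicate 1. As a covariate, the mean log2(FPKM + 1) of the same markers was used instead. It ran from 1.23 to 1.46 at E17.5 and from 2.7 to 8.24 at P14. The ages did not overlap in it, so the age effect in that fit rests on extrapolation. Its slope was set mostly by the P14 libraries, with P14 replicate 1 furthest out. Ratios of P14 replicate 1 to the other P14 libraries were taken per gene against the mean of those 3, for genes with a mean FPKM of 1 or more there.

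The alternatives fixed then were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of 5 or more, rescaling to TPM, median-of-ratios scaling, quantile normalization, protein-coding genes alone, no trend or robust moderation, array weights, the replicate number as a block, each library left out in turn, the estimated correlation and fry. Those added after the data had been seen were the subtraction of the epithelial share together with leaving out P14 replicate 1, leaving out P14 replicates 1 and 3, the epithelial level as a covariate, voom on the recovered reads, and the estimated correlation without P14 replicate 1. In the subtraction, the P14 replicate 1 profile times each other P14 library's epithelial level was taken off, and each library was rescaled so that its median tested gene kept its level.

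The test was tried on simulated data for the 14044 genes, with counts drawn around the mean E17.5 levels at the real library sizes. For 4 libraries against 4, 98.5% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold were called, with 13 false calls, and 1 gene was called when none was changed. For 4 against 3 the shares were 94%, 100% and 98.5%, with 15 false calls and 4 when none was changed. The simulated spread had 1 dispersion, estimated from the E17.5 libraries, so the tried case does not cover the spread seen at P14.

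Splice forms, isoforms and exon use were not analysed here, because the values are per gene. The 4 Y-linked genes read for a check of the libraries were not among the tested genes. Xist, read for the same check, was tested like any other gene.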

Results

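RNA was sequenced from the mesenchyme of the mouse small intestine, the compartment of muscle, nerves, vessels and connective tissue cells left once EDTA had detached the epithelium. All animals were wild type. 4 libraries came from fetuses at E17.5 and 4 from pups at postnatal day 14 (P14), ages on either side of birth. The study concerned gut lengthening and the proteins SLMAP and MST3, the latter encoded by Stk24, and its design named the spliceosome and alternative splicing. A table of 1 value per gene cannot show splice forms, so the comparison of the ages covered the levels of splicing factors and of other gene groups.

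The reads assigned to genes were 16.7e+06 to 19.5e+06 per library at E17.5 and 17.7e+06 to 18.5e+06 at P14. The number of genes above 0 FPKM lay between 23086 and 25186 per library. Mitochondrial genes took 2.2% to 3.54% of the assigned reads at E17.5 and 3.25% to 4.61% at P14. Across the 14044 tested genes, the E17.5 libraries correlated with each other at 0.974 to 0.987 and P14 replicates 2, 3 and 4 at 0.956 to 0.974. P14 replicate 1 correlated with the other P14 libraries at 0.78 to 0.873 only. These are correlations across genes within pairs of libraries, and genes are not independent replicates.

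Epithelial transcripts differed widely between the P14 libraries. With the level in P14 replicate 1 set to 100%, the median level of the pan-epithelial markers was 1.34% in replicate 2, 14% in replicate 3 and 4.65% in replicate 4. At E17.5 it lay between 0.268% and 0.454%. Transcripts of the gut wall were lower in P14 replicate 1 than in the mean of the other P14 libraries, with median ratios of 0.33 for smooth muscle genes, 0.32 for enteric neuron genes, 0.37 for interstitial collagens and 0.15 for mesothelial genes. The ratio was 1.7 for B and plasma cell genes and 1.4 for T and NK genes. For that reason each count was also made without P14 replicate 1, and the second value is given beside the first. Leaving out each library in turn was fixed in advance. Printing this omission beside the main values was chosen after the epithelial levels had been seen.

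The comparison of P14 with E17.5 found lists of genes of absorptive epithelium, antibody-producing cells and mitochondria higher at P14, and of cell division, fetal growth, hedgehog response and macrophages higher at E17.5. These lists passed camera with its preset correlation, and of all 41 tested lists only fetal growth passed with an estimated correlation (adjusted p = 0.032 with an estimated correlation). Epithelium is the tissue that EDTA was meant to remove, and the epithelial level did not overlap between the ages. For epithelial genes, age therefore cannot be told apart from the amount of epithelium left. With limma and Benjamini-Hochberg adjustment, 3473 of 14044 genes changed, 1365 up and 2108 down. At least 2-fold changes were found for 508 genes up and 499 down. Without P14 replicate 1 the counts were 6958, with 3176 up and 3782 down, and at least 2-fold changes in 771 and 416 genes. Of the 3473 genes, 3469 were called in both. The total was 1735 without E17.5 replicate 3, 2001 without E17.5 replicate 4, 2041 without E17.5 replicate 2 and 2223 without P14 replicate 3. In those 4 settings the increases numbered 617, 723, 753 and 805, and they numbered 895 without E17.5 replicate 1 and 890 without P14 replicate 4. Decreases numbered 1118, 1278 and 1288 without E17.5 replicates 3, 4 and 2, and increases of at least 2-fold numbered 285, 301, 337 and 331 without E17.5 replicates 3, 4 and 2 and P14 replicate 3. Rescaling to TPM moved the median of all tested genes by -0.18 on the log2 scale and gave 899 genes up and 2678 down, so the share of increases went from 39.3% to 25.1%. Fold changes below are P14 against E17.5 on the log2(FPKM + 1) scale, with SE, and values after ± are SDs over the 4 libraries of an age (n = 4).

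The 12 protein-coding genes with the largest increases were Apoa1, Apoa4, Guca2a, Clca4b, Folr1, Meltf, Alpi, Cdhr5, Spink1, Lypd8, Naaladl1 and Epcam. Apoa1 and Apoa4 encode apolipoproteins of lipid-absorbing enterocytes, Alpi encodes intestinal alkaline phosphatase, and Epcam encodes an epithelial adhesion protein. Apoa1 (chromosome 9, 46139928 to 46141767) reached 5971 FPKM in P14 replicate 1, 1024 in replicate 3, 413 in replicate 4 and 70.7 in replicate 2, against 1.74 ± 0.68 at E17.5 (log2 fold change 7.93, SE 1.16, adjusted p = 0.00353). Epcam (chromosome 17, 87943407 to 87958555) was at 1228, 118, 33.5 and 8.46 FPKM in P14 replicates 1, 3, 4 and 2, the order of the epithelial level, which it helps to set as a marker, and at 1.14 ± 0.475 at E17.5 (5.3, SE 1.3, adjusted p = 0.0223). The calls of Clca4b, Cdhr5, Naaladl1 and Epcam were lost without E17.5 replicate 3, with adjusted p of 0.0525, 0.0512, 0.0696 and 0.0651. That of Clca4b was also lost without E17.5 replicate 4 (0.0507), and those of Naaladl1 and Epcam without any one of E17.5 replicates 1, 2 and 4 and P14 replicate 3 (lowest adjusted p 0.0577 and 0.0539). When the epithelial share was subtracted and P14 replicate 1 left out, an alternative added after the data had been seen, 9 of the 12 log2 fold changes fell below 0. The exceptions were Apoa1 (3.55, adjusted p = 0.183), Apoa4 (3.7, adjusted p = 0.208) and Lypd8 (2.3, adjusted p = 0.173). The subtracted share is set from the pan-epithelial markers, Cdhr5 and Epcam among them, so falls of epithelial genes to about 0 were largely built in.

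The 12 largest decreases were in Col6a5, Ccl11, Rps2, Actc1, Col6a4, Foxl1, Gzma, Tmem255a, Mest, Stc2, Ednrb and Ccl24. Col6a5 (chromosome 9, 105733269 to 105839743), a collagen VI chain, was at 59.0 ± 7.52 FPKM at E17.5 and 2.07 ± 1.32 at P14 (-4.36, SE 0.257, adjusted p = 0.000263). Its relative Col6a4 went from 190 ± 24.6 to 16.1 ± 9.7 FPKM. Ccl11 and Ccl24, chemokines that attract eosinophils, had log2 fold changes of -4.26 (SE 0.258) and -2.61 (SE 0.241). Actc1, the cardiac actin gene, fell by 3.75 (SE 0.741), and Stc2, which encodes a stanniocalcin, by 2.7 (SE 0.266). Gzma, a granzyme of killer lymphocytes, went from 10.7 ± 2.16 to 0.316 ± 0.269 FPKM, and Tmem255a from 29.96 ± 5.31 to 2.63 ± 0.666. The value of Rps2, a ribosomal protein gene with 10 named copies in the same table, is uncertain: P14 replicate 3 held 339 FPKM and the other P14 libraries 9.21 to 13.4, against 541 ± 101 at E17.5, and the call was lost without any one E17.5 library, P14 replicate 2 or P14 replicate 4 (adjusted p 0.0517 to 0.0645).

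Of the genes the study is named for, neither passed the test with all libraries. Slmap (gene 83997, chromosome 14, 26134323 to 26256103, minus strand), which encodes a membrane-anchored adaptor, was at 21.5, 22.1, 26.9 and 27.5 FPKM in E17.5 replicates 1 to 4 and at 23.4, 39.3, 32.4 and 36.2 in P14 replicates 1 to 4. The means were 24.5 ± 3.17 and 32.8 ± 6.89 (log2 fold change 0.39, SE 0.175, adjusted p = 0.139). Stk24 (gene 223255, chromosome 14, 121521599 to 121618269, minus strand), the gene of the kinase MST3, was at 16.7, 16.4, 17.15 and 17.53 FPKM at E17.5 and at 22.4, 19.6, 20.99 and 19.8 at P14. All 4 P14 values lay above all 4 E17.5 values, a full separation that counted in both directions has an exact permutation p of 0.0286, and the log2 fold change was 0.27 (SE 0.086, adjusted p = 0.0506). Without P14 replicate 1 both rose: Slmap by 0.54 (SE 0.113, adjusted p = 0.00491; 35.9 ± 3.46 FPKM over 3 libraries) and Stk24 by 0.24 (SE 0.0644, adjusted p = 0.0155). With all libraries and rescaling to TPM, the log2 fold change of Stk24 was 0.09.

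**Figure D1:**
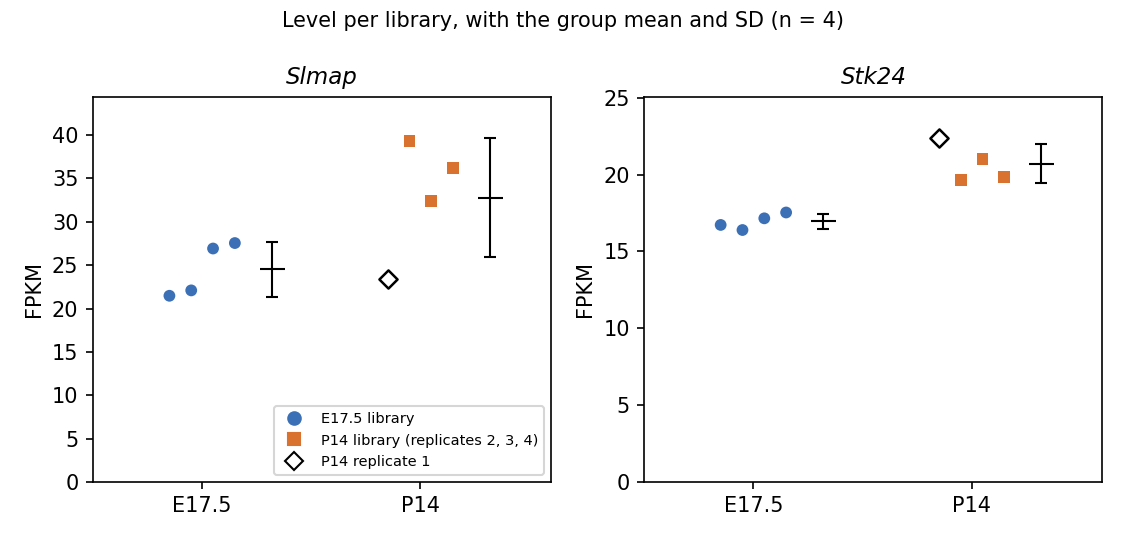
FPKM of Slmap and Stk24 (vertical axes, from 0) in each library at E17.5 and P14 (horizontal axes), with the mean and SD of the 4 libraries of each age beside the points. Slmap lay between 21.5 and 27.5 FPKM at E17.5 and between 32.4 and 39.3 in P14 replicates 2 to 4, with 23.4 in P14 replicate 1 (open diamond), and Stk24 between 16.4 and 17.53 at E17.5 and between 19.6 and 22.4 at P14.

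Slmap and Stk24 belong to STRIPAK, a complex of phosphatase PP2A with striatins and kinases. Of its 19 tested members, Cttnbp2nl, a striatin-binding protein, fell by 0.96 (SE 0.121, adjusted p = 0.00186) and Stk26, the gene of the kinase MST4, rose by 0.60 (SE 0.152, adjusted p = 0.0255). The Stk26 call was lost without any one of E17.5 replicates 1, 2 and 3 and P14 replicates 3 and 4 (adjusted p 0.0594 to 0.0713). The other 17 did not pass, and the counts adjusted over the list alone were also 1 up and 1 down. The member with the highest level was Ppp2ca, a catalytic subunit of PP2A, at 148 ± 10.6 and 136 ± 21.7 FPKM (adjusted p = 0.476). Without P14 replicate 1, 3 members were up and 5 down, beside 3176 up and 3782 down among all 14044 tested genes. The list did not stand apart from other genes by camera (adjusted p = 0.622). Its mean level was 4.32 ± 0.084 at E17.5 and 4.25 ± 0.058 at P14 on the log2 scale, a difference of -0.07 (exact two-sided permutation p = 0.286, smallest possible 0.0286), and -0.09 without P14 replicate 1 (exact p = 0.171).

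Genes of the Hippo pathway, to which STRIPAK is linked, fell as a set (24 tested members, median -0.33, camera adjusted p = 0.0251; adjusted p = 0.22 with an estimated correlation). The list mixes the kinase cascade that restrains YAP and TAZ with its targets, Yap1, Wwtr1 (the gene of TAZ) and the TEAD genes. The set test therefore does not by itself show that the restraining cascade fell. With all libraries, members of the cascade were among the called decreases beside Yap1 and Tead2, and the 1 called increase was also in the cascade. 1 member rose and 6 fell (2 and 10 adjusted over the list alone), against 3 and 13 without P14 replicate 1. Tead2, a TEAD transcription factor, went from 58.1 ± 6.95 to 26.7 ± 10.4 FPKM, Map4k4, an upstream kinase, fell by 0.72 (SE 0.163), and Yap1, the co-activator itself, from 45.5 ± 0.924 to 31.5 ± 4.18 FPKM. The Tead2 call was lost without any one E17.5 library or P14 replicate 4 (adjusted p 0.0532 to 0.0794), that of Map4k4 without E17.5 replicate 2 or 3 (0.051 and 0.0506) and that of Yap1 without E17.5 replicate 3 (0.0544). Mob1a, a kinase co-activator and the member with the highest level, was at 52.9 ± 4.84 and 35.1 ± 10.8 FPKM (adjusted p = 0.0504, and 0.00021 without P14 replicate 1). Rescaled to TPM, the set had an adjusted p of 0.0543.

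Among 21 tested YAP and TAZ target genes, 1 rose and 5 fell (2 and 7 adjusted over the list alone), and 4 rose and 8 fell without P14 replicate 1. Nt5e, the ecto-nucleotidase CD73, rose from 9.36 ± 1.22 to 34.2 ± 10.2 FPKM. Foxf2, a forkhead factor of gut mesenchyme, fell by 1.34 (SE 0.25), and Igfbp3, an IGF-binding protein, from 163 ± 11.7 to 72.0 ± 8.16 FPKM. Against other genes the list did not pass camera with all libraries (median -0.32, adjusted p = 0.0908) or without P14 replicate 1 (median -0.16, adjusted p = 0.33). It passed camera narrowly without P14 replicate 4 (0.05 after rounding). As a list on its own it missed the threshold by fry with all libraries (adjusted p = 0.054) and was lower without P14 replicate 1 (0.000461). Its mean level per library was 4.19 ± 0.012 at E17.5 and 3.94 ± 0.21 at P14 on the log2 scale. The exact permutation p of that level was 0.0286, the smallest possible, with all libraries and without P14 replicate 1.

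Most core spliceosome components did not pass the test. Of 108 tested members, 2 rose, 13 fell and 93 did not pass (2 up and 12 down adjusted over the list alone), beside decreases in 2108 of all 14044 tested genes. The list was lower than other genes by camera (adjusted p = 0.0365; adjusted p = 0.43 with an estimated correlation). The median log2 fold change was -0.13, and the mean level was 4.61 ± 0.063 at E17.5 and 4.5 ± 0.012 at P14. Snrpd1, a core protein of spliceosomal snRNPs, went from 85.0 ± 11.5 to 51.9 ± 6.13 FPKM, and Dhx15, a helicase that takes spliceosomes apart, fell by 0.63 (SE 0.105, adjusted p = 0.0053). Lsm4, a U6 snRNP protein, went the other way, from 16.2 ± 3.26 to 25.4 ± 2.79 FPKM, a call lost without any one of E17.5 replicates 2, 3 and 4 and P14 replicates 2, 3 and 4 (adjusted p 0.0554 to 0.0613). Snrpb, the member with the highest level, was at 92.6 ± 9.79 and 106 ± 18 FPKM (log2 fold change 0.19, adjusted p = 0.384, and 0.0323 without P14 replicate 1, turning to -0.00463 after TPM rescaling and -0.0113 after quantile normalization).

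The camera call of the spliceosome list was lost without E17.5 replicate 1 or 2 (adjusted p = 0.0707 each) or P14 replicate 3 (0.0541), and after median-of-ratios scaling (0.0543). The difference in mean level, -0.10 on the log2 scale, had an exact two-sided permutation p of 0.0286, the smallest possible. It was -0.11 without P14 replicate 1 (exact p = 0.0857), and the exact p was also 0.0857 without each other P14 library. Without P14 replicate 1, 6 members were up and 30 down, beside 3176 up and 3782 down among all 14044 tested genes.

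Heterogeneous nuclear ribonucleoproteins (hnRNPs), which bind nascent transcripts and affect exon choice, were lower than other genes by camera (median -0.25, adjusted p = 0.00315; adjusted p = 0.34 with an estimated correlation). None was called up and 8 of 26 were called down (10 adjusted over the list alone), and 13 down without P14 replicate 1. Hnrnpa3 went from 29.9 ± 3.36 to 13.7 ± 1.22 FPKM, Hnrnpa1 from 228 ± 26.5 to 130 ± 14.7, and Hnrnpll fell by 0.66 (SE 0.107). Hnrnpa1 and Hnrnpa3 belong to a family rich in processed pseudogenes, so their values are uncertain where reads were shared. Hnrnpk was at 216 ± 6.11 and 175 ± 16.6 FPKM (adjusted p = 0.0565, and 0.0246 without P14 replicate 1).

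SR proteins and their kinases, which mark exons for inclusion, went in both directions, with 2 of 20 up and 4 down (2 and 5 adjusted over the list alone), and 2 up and 7 down without P14 replicate 1. Srsf5, an SR protein, rose from 176 ± 13.2 to 257 ± 4.72 FPKM, and Srpk3, a muscle-enriched SR protein kinase, from 0.696 ± 0.19 to 3.19 ± 0.422. Tra2a and Srsf7, both splicing activators, fell by 0.62 (SE 0.14) and 0.56 (SE 0.103), the first not without E17.5 replicate 3 (adjusted p = 0.0576). The list as a whole did not pass (median -0.19, camera adjusted p = 0.141).

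Of 31 tested tissue-restricted splicing regulators, 1 was up and 7 were down, as also when adjusted over the list alone. Ptbp1, a repressor of neuronal and muscle exons, went from 144 ± 7.38 to 97.9 ± 6.86 FPKM (adjusted p = 0.00572). Qk, Tia1 and Nova2, RNA-binding regulators of exon choice, fell by 0.86 (SE 0.263), 0.67 (SE 0.17) and 0.60 (SE 0.178). The calls of Qk and Nova2 were lost without any one library other than P14 replicate 1 (adjusted p 0.0572 to 0.124 and 0.0524 to 0.109). That of Tia1 was lost without any one of E17.5 replicates 2, 3 and 4 and P14 replicates 3 and 4 (0.0546 to 0.0817). The list had a median of -0.23 (camera adjusted p = 0.199), and 9 members up and 10 down with a median of 0.03 and the test direction up (0.98) without P14 replicate 1. With the epithelial level as a covariate, a setting added after the data had been seen, the list was higher at P14 (adjusted p = 0.0392). That covariate did not overlap between the ages. Of 13 nonsense-mediated decay factors, which remove transcripts with early stop codons, 2 were up and 1 down, also when adjusted over the list alone, and 3 were up and 4 down without P14 replicate 1. Their median was -0.04 while their mean, 0.04, and the direction of the test were positive (camera adjusted p = 0.764), the direction turning without P14 replicate 1 (median -0.09, adjusted p = 0.98).

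**Figure D2:**
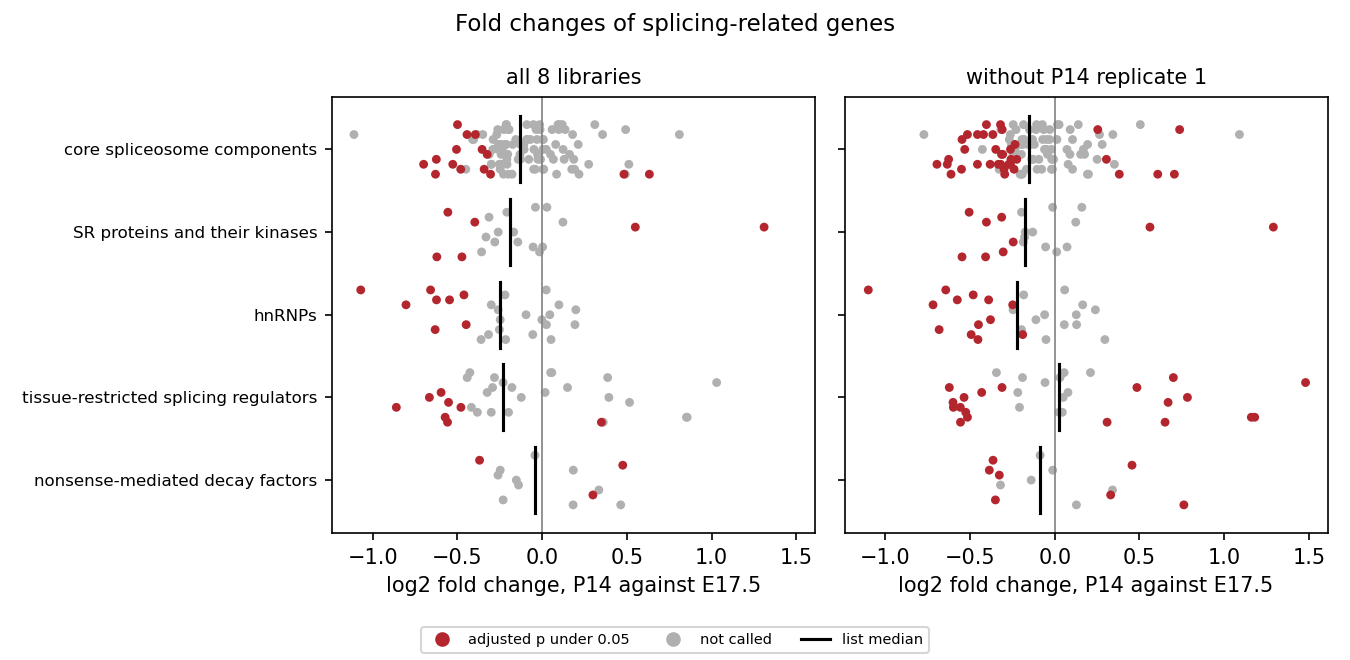
Log2 fold change of P14 against E17.5 (horizontal axes) for each tested member of 5 splicing-related lists (vertical axis), with all 8 libraries on the left and without P14 replicate 1 on the right. Each point is a gene, red where its adjusted p was under 0.05, and black bars are list medians, which with all 8 libraries were -0.13 for the core spliceosome, -0.19 for SR proteins and their kinases, -0.25 for hnRNPs, -0.23 for tissue-restricted regulators and -0.04 for decay factors.

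Both lists of cell division genes were lower at P14 by camera, mitosis at adjusted p = 3.65e-14 (adjusted p = 0.43 with an estimated correlation) and replication at 4.07e-07 (adjusted p = 0.45 with an estimated correlation). Of 38 tested mitosis genes none rose and 33 fell (36 adjusted over the list alone; 37 without P14 replicate 1), with a median of -1.01. Ccnb1, the gene of cyclin B1, went from 40.1 ± 4.73 to 13.0 ± 4.09 FPKM, Top2a, the topoisomerase of dividing cells, from 76.9 ± 7.14 to 28.1 ± 7.13, and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, from 118 ± 16.2 to 52.0 ± 10.8. Cenpe, a kinetochore motor, fell by 1.57 (SE 0.199). Among 40 DNA replication genes 16 fell and none rose (20 down adjusted over the list alone; 25 without P14 replicate 1). Mcm3 and Mcm4, subunits of the replicative helicase, fell by 0.87 (SE 0.188) and 0.98 (SE 0.22), and Rrm1, a subunit of ribonucleotide reductase, by 0.90 (SE 0.226). The adjusted p of Mcm4 was 0.054 without E17.5 replicate 3, and that of Rrm1 0.0547 to 0.0713 without any one E17.5 library or P14 replicate 3. Pcna, the sliding clamp, was at 138 ± 14.7 and 112 ± 5.58 FPKM (adjusted p = 0.0846, and 0.0459 without P14 replicate 1).

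Fetal growth and imprinted genes fell as a set, the single list that passed with the preset and the estimated correlation (camera adjusted p = 1.34e-07; adjusted p = 0.032 with an estimated correlation), although the latter was 0.066 without P14 replicate 1. Of 22 tested members none rose and 14 fell (15 adjusted over the list alone), with a median of -1.35; 1 rose and 17 fell without P14 replicate 1. H19 (chromosome 7, 142129267 to 142131883, minus strand), an imprinted long non-coding RNA, went from 1097 ± 57.4 to 138 ± 17.8 FPKM (-2.99, SE 0.114, adjusted p = 5.13e-05). Igf2, the neighbouring gene of a fetal growth factor, went from 237 ± 9.98 to 51.2 ± 13.3 FPKM. Mest, an imprinted gene, went from 38.9 ± 3.08 to 4.37 ± 1.39 FPKM, and Hmga2, a chromatin protein of fetal cells, from 9.36 ± 0.905 to 0.843 ± 0.825. H19 and Igf2 lie side by side on the same strand.

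Growth factor genes of the IGF, FGF, PDGF and TGF-beta families had 1 of 25 members up and 8 down (1 and 9 adjusted over the list alone; 5 up and 12 down without P14 replicate 1). Igf1, insulin-like growth factor 1, went from 21.2 ± 2.05 to 6.42 ± 1.62 FPKM, and Pdgfrb, a PDGF receptor of pericytes and fibroblasts, from 39.4 ± 4.72 to 16.1 ± 3.34, beside Igfbp3 above. Igfbp7 was at 239 ± 19 and 346 ± 124 FPKM (adjusted p = 0.29, and 0.000501 without P14 replicate 1). By camera the list was lower than other genes (median -0.36, adjusted p = 0.0284, and adjusted p = 0.59 with an estimated correlation), but not without P14 replicate 1 (median -0.17, adjusted p = 0.33). As a list on its own it was still lower without P14 replicate 1. Fry gave adjusted p = 0.000785, and the mean level per library differed by -0.118 (exact permutation p = 0.0286).

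Smooth muscle genes stood above other genes at P14 by camera (adjusted p = 0.000445; adjusted p = 0.69 with an estimated correlation). As a list on their own they did not pass with all libraries, by fry (adjusted p = 0.279) or by the mean level per library (exact permutation p = 0.143), and did without P14 replicate 1 (0.000625 and 0.0286). The median of 41 tested members was 0.62 with 4 up and none down (2 up adjusted over the list alone), and 0.97 with 35 up and 2 down without P14 replicate 1, the library with the high epithelial level. Pcp4, a calmodulin regulator, went from 42.8 ± 6.45 to 234 ± 103 FPKM, and Synm, an intermediate filament protein, from 22.4 ± 0.38 to 78.7 ± 34.1. Pgm5, a protein of muscle adhesion sites, rose by 1.11 (SE 0.329), a call lost without any one library other than P14 replicate 1 (adjusted p 0.0825 to 0.106). Actg2, the enteric smooth muscle actin and the member with the highest level, was at 2658 ± 106 and 3315 ± 1550 FPKM (0.14, adjusted p = 0.814, and 0.00571 without P14 replicate 1, but -0.05 after TPM rescaling, -0.34 after quantile normalization, -0.08 without P14 replicate 2 and -0.02 without P14 replicate 4). Myh11, smooth muscle myosin, and Acta2, another actin, named here after their values were seen, had log2 fold changes of 1.09 (adjusted p = 0.059) and 0.74 (adjusted p = 0.211), and rose by 1.49 (adjusted p = 3.09e-05) and 1.19 (adjusted p = 0.000179) without P14 replicate 1. The list's camera adjusted p was 1.29e-13 without P14 replicate 1 (adjusted p = 0.45 with an estimated correlation).

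Enteric neuron genes had 5 of 33 members up and 1 down (4 and 1 adjusted over the list alone), and 20 up and 4 down without P14 replicate 1. Calb2 (chromosome 8, 110869158 to 110894844), the gene of calretinin, went from 0.072 ± 0.0392 to 28.4 ± 11.9 FPKM (4.65, SE 0.35, adjusted p = 0.000414). Gal, the neuropeptide galanin, went from 16.95 ± 1.66 to 112 ± 52.8 FPKM, and Scg2, a secretory granule protein, from 11.5 ± 0.979 to 45.6 ± 17.3. Uchl1, a neuronal ubiquitin hydrolase, was at 89.3 ± 9.28 and 113 ± 54.4 FPKM (0.15, adjusted p = 0.827, and 0.00252 without P14 replicate 1, but -0.05 after TPM rescaling, -0.09 without P14 replicate 2 and -0.00165 without P14 replicate 3). The list had a median of 0.18 (camera adjusted p = 0.0853), and of 0.60 without P14 replicate 1 (camera adjusted p = 1.43e-05; the estimated correlation gave adjusted p = 0.45).

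Of 14 enteric glia genes 5 were up and 1 was down, as also when adjusted over the list alone, and 9 and 1 without P14 replicate 1. Entpd2, an ecto-nucleotidase, went from 6.16 ± 0.44 to 27.4 ± 16.3 FPKM, highest in P14 replicate 1 at 51.7, and Scn7a, a sodium channel, from 0.818 ± 0.213 to 4.26 ± 1.29. Ednrb, the endothelin receptor needed for neural crest colonisation of the gut, went the other way, from 129 ± 16.7 to 20.2 ± 4.86 FPKM. Apoe was at 216 ± 51.4 and 152 ± 33.6 FPKM (adjusted p = 0.127). Among 11 genes of interstitial cells of Cajal, the pacemaker cells of gut motility, 3 rose and none fell, also when adjusted over the list alone, against 6 and 2 without P14 replicate 1. Prkcq, a protein kinase C, went from 2.73 ± 0.252 to 11.01 ± 4.43 FPKM. Kit, the receptor these cells need, and Gpr20, an orphan receptor, rose by 1.24 (SE 0.334) and 1.11 (SE 0.331), calls lost without any one library other than P14 replicate 1 (adjusted p 0.0663 to 0.0818 for Kit and 0.0874 to 0.11 for Gpr20). Col18a1 was at 60.9 ± 10.9 and 36.2 ± 11.4 FPKM (adjusted p = 0.0659, and 0.0134 without P14 replicate 1). Neither list passed camera with all libraries (adjusted p = 0.205 for glia and 0.32 for Cajal cells), and both did without P14 replicate 1 (0.0329 and 0.0227; with an estimated correlation, adjusted p = 0.41 and adjusted p = 0.45).

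Mesothelial genes, of the outer lining of the gut, had 2 of 9 up and none down, also when adjusted over the list alone, and 8 up without P14 replicate 1. Cldn15, a tight junction protein that the epithelium also makes, went from 5.35 ± 1.08 to 18.1 ± 4.15 FPKM, and Krt7, a keratin, from 9.58 ± 2.5 to 31.8 ± 21.9, a call lost without any one E17.5 library or P14 replicate 3 (adjusted p 0.0616 to 0.0921). Upk3b, a uroplakin of mesothelium, was at 30.4 ± 5.23 and 48.6 ± 27.7 FPKM, with 8.37 in P14 replicate 1 and 53.0 to 70.03 in the other P14 libraries (adjusted p = 0.721, and 0.000702 without P14 replicate 1). The camera adjusted p was 0.088, 0.0467 without E17.5 replicate 4, and 0.000552 without P14 replicate 1 (adjusted p = 0.45 with an estimated correlation).

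**Figure D3:**
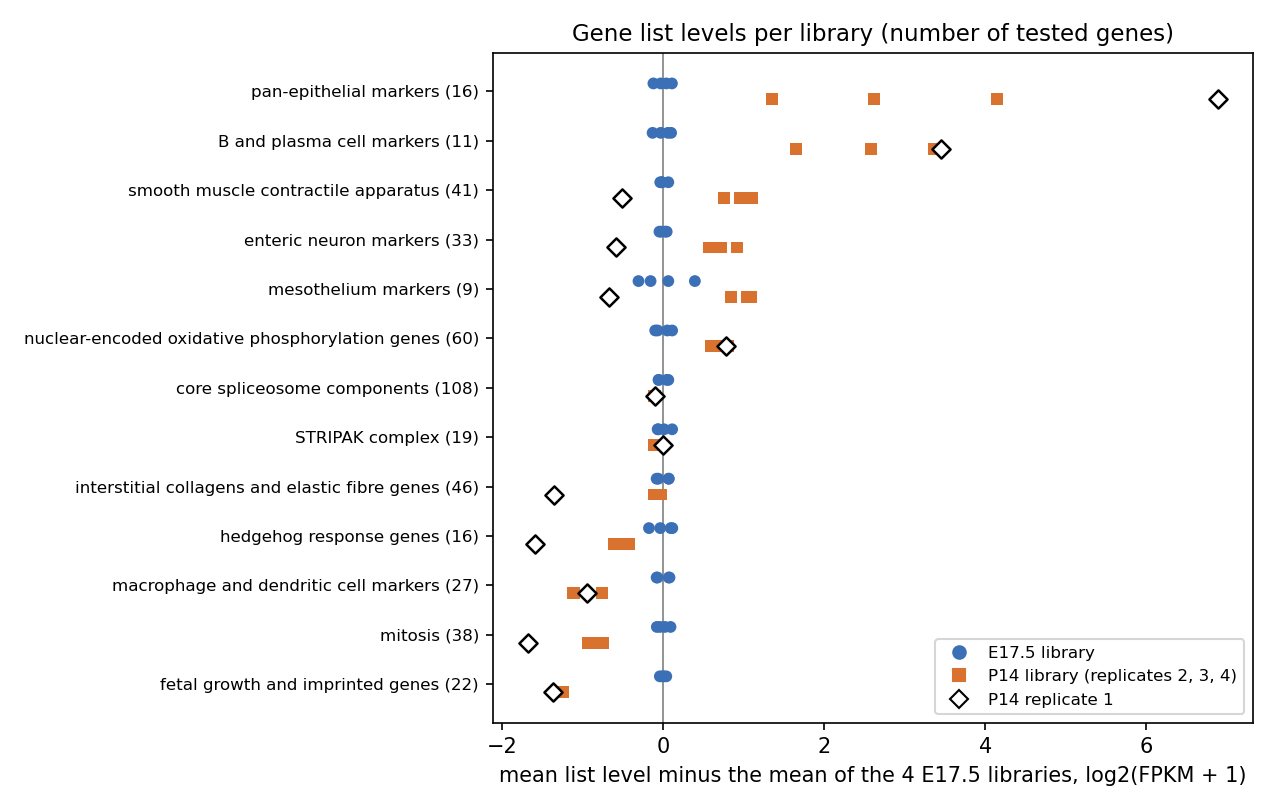
Mean log2(FPKM + 1) of the tested genes of 13 lists in each library, minus the mean of the 4 E17.5 libraries (horizontal axis), with the list name and its number of tested genes on the vertical axis. Circles are E17.5 libraries, squares P14 replicates 2, 3 and 4, and the open diamond P14 replicate 1; the mean difference at P14 was 3.75 for pan-epithelial markers, 0.58 for smooth muscle, 0.73 for oxidative phosphorylation, -0.10 for the core spliceosome, -1.04 for mitosis and -1.29 for fetal growth and imprinted genes.

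Of 46 interstitial collagen and elastic fibre genes 3 rose and 14 fell, also when adjusted over the list alone, against 12 and 18 without P14 replicate 1. Lox, the enzyme that cross-links collagen and elastin, went from 57.7 ± 4.34 to 14.8 ± 6.24 FPKM, Fbn2, fetal fibrillin, from 54.1 ± 3.27 to 15.7 ± 6.46, and P4ha1, a collagen prolyl hydroxylase, from 36.7 ± 2.79 to 9.81 ± 2.19. Sparc, a matrix protein and the member with the highest level, was at 873 ± 54.3 and 782 ± 274 FPKM (-0.25, adjusted p = 0.558, and 0.07 without P14 replicate 1). By camera the set was lower with all libraries (median -0.51, adjusted p = 0.0141; adjusted p = 0.77 with an estimated correlation; fry adjusted p = 0.279), but not without P14 replicate 1 (median -0.17, adjusted p = 0.33) or after TPM rescaling (adjusted p = 0.106). With the epithelial level as a covariate, a setting added after the data had been seen, the set was higher at P14 (adjusted p = 0.00445). That covariate did not overlap between the ages, so this result rests on extrapolation.

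Of 20 basement membrane genes none rose and 6 fell (9 adjusted over the list alone), against 4 and 11 without P14 replicate 1. Nid2, a nidogen, went from 58.4 ± 4.26 to 25.2 ± 3.54 FPKM, Lamb1, a laminin chain, from 164 ± 4.36 to 77.9 ± 21.7, and Col4a6, a collagen IV chain, from 5.26 ± 0.28 to 2.01 ± 0.902. Col4a1 was at 313 ± 16.1 and 226 ± 74.3 FPKM (adjusted p = 0.167, and 0.0296 without P14 replicate 1). By camera the set was lower than other genes with all libraries (median -0.51, adjusted p = 0.0164, and adjusted p = 0.6 with an estimated correlation). It did not pass camera without P14 replicate 1 (median -0.28, adjusted p = 0.107) or after TPM rescaling. As a list on its own it was still lower without P14 replicate 1. Fry gave adjusted p = 0.000722, and the mean level per library differed by -0.249 (exact permutation p = 0.0286).

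Hedgehog response genes, which read the epithelial signal to the mesenchyme, were lower than other genes at P14 by camera (adjusted p = 0.0022, and adjusted p = 0.59 with an estimated correlation). The list also holds components of the pathway, such as Smo and Sufu, so the set test does not by itself show a lower response. Of 16 tested members none rose and 7 fell, also when adjusted over the list alone, with a median of -0.77, and 4 rose and 11 fell without P14 replicate 1, with a median of -0.42. Ptch1, the hedgehog receptor and itself a target, went from 94.1 ± 6.05 to 23.02 ± 5.91 FPKM, Hhip, a hedgehog-binding inhibitor, from 23.1 ± 2.42 to 5.33 ± 2.03, and Foxl1, a forkhead factor of subepithelial cells, from 21.8 ± 4.94 to 1.54 ± 0.83. Nkx2-3, a homeobox gene of gut mesenchyme, fell by 1.35 (SE 0.296). The camera adjusted p was 0.035 without P14 replicate 1. With the epithelial share also subtracted the camera test did not pass (0.154), with a median of -0.37, 4 up and 10 down, and the direction turned up with the epithelial level as a covariate (0.907), both settings added after the data had been seen.

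Fibroblast signals to the epithelium went both ways. Of 32 tested members 4 rose and 11 fell (5 and 12 adjusted over the list alone), and 12 rose and 12 fell without P14 replicate 1. C3, the central complement component, went from 8.48 ± 2.26 to 102 ± 55.0 FPKM (3.17, SE 0.57), with 21.7 in P14 replicate 1 and 116 to 147 in the others. Adamdec1, a metalloprotease of gut fibroblasts, went from 1252 ± 39.3 to 281 ± 209 FPKM, with 95 and 110 in P14 replicates 2 and 4 and 425 and 496 in replicates 1 and 3. As a set the list did not pass (median -0.33, camera adjusted p = 0.0622), but it did without P14 replicate 2 (0.0377), 3 (0.0111) or 4 (0.0252), while the median was -0.18 and the adjusted p 0.98 without P14 replicate 1. Of 27 genes of WNT5A signalling and planar cell polarity, which orient cells in the tissue plane, none rose and 3 fell, also when adjusted over the list alone, against 7 and 8 without P14 replicate 1. Sfrp1, a secreted WNT antagonist, went from 94.2 ± 5.77 to 18 ± 7.02 FPKM, and Fat4 and Ptk7, a protocadherin and a receptor of polarity signalling, fell by 1.19 (SE 0.188) and 1.01 (SE 0.254). The Ptk7 call was lost without E17.5 replicate 1, 2 or 3, with adjusted p of 0.0585 to 0.069. The list as a whole did not pass (median -0.15, camera adjusted p = 0.152, and median -0.02 and adjusted p = 0.9 without P14 replicate 1), and it was higher at P14 with the epithelial level as a covariate, a setting added after the data had been seen (0.0482). That covariate did not overlap between the ages.

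Both endothelial lists were lower at P14 by camera, blood vessels at adjusted p = 0.000131 (adjusted p = 0.59 with an estimated correlation) and lymphatics at 0.00357 (adjusted p = 0.43 with an estimated correlation). Of 25 blood endothelium genes 1 rose and 12 fell (1 and 14 adjusted over the list alone; 4 and 15 without P14 replicate 1), with a median of -0.79. Kdr and Flt1, receptors of vascular endothelial growth factor, went from 60.2 ± 7.2 to 24.3 ± 6.75 and from 20.8 ± 2.03 to 7.12 ± 1.89 FPKM, and Gja5, an arterial connexin, from 11.2 ± 1.1 to 3.08 ± 2.08. Plvap, of the diaphragms of fenestrated vessels, was at 244 ± 25.5 and 148 ± 51.8 FPKM (adjusted p = 0.0659, and 0.00944 without P14 replicate 1). Of 11 lymphatic genes none rose and 6 fell, also when adjusted over the list alone, against 1 and 6 without P14 replicate 1. Lyve1, a hyaluronan receptor, went from 54.9 ± 3.4 to 15.7 ± 3.04 FPKM, and Flt4, the lymphatic growth factor receptor, and Mmrn1, a multimerin, fell by 1.37 (SE 0.19) and 1.32 (SE 0.184). Ccl21a, a chemokine with near-identical copies and thus uncertain, was at 88.8 ± 21.2 and 56.8 ± 31.7 FPKM (adjusted p = 0.255).

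Macrophage and dendritic cell genes were lower at P14 by camera (adjusted p = 6.38e-10; adjusted p = 0.22 with an estimated correlation). Of 27 macrophage and dendritic cell genes none rose and 22 fell, also when adjusted over the list alone, against 1 and 23 without P14 replicate 1, and the median was -1.05. Fcgr1, an Fc receptor, went from 7.13 ± 0.733 to 1.03 ± 0.323 FPKM, Cx3cr1, a fractalkine receptor, from 19.7 ± 1.49 to 5.84 ± 1.3, and Ccr2, the monocyte chemokine receptor, fell by 1.84 (SE 0.232). Lyz2, a lysozyme of macrophages, was at 86.5 ± 10.5 and 95.7 ± 38.2 FPKM (0.04, adjusted p = 0.944, turning to -0.16 after TPM rescaling, -0.17 after quantile normalization, -0.15 without P14 replicate 1, -0.06 without P14 replicate 3, -0.02 without P14 replicate 4 and -0.02 without E17.5 replicate 1).

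Of 11 B and plasma cell genes 7 rose and 1 fell, also when adjusted over the list alone, against 6 and 1 without P14 replicate 1 (camera adjusted p = 5.36e-05; adjusted p = 0.34 with an estimated correlation). Igkc, the kappa light chain, was at 0.733 ± 0.821 FPKM at E17.5 and 215 ± 88.9 at P14. Igha, the heavy chain of IgA, was above 0 in 1 E17.5 library, at 0.172, and at 73.0 ± 38.2 FPKM at P14. Iglc2, a lambda light chain gene with near-identical neighbours and thus uncertain, was listed at 0 in all 4 E17.5 libraries and at 1.73 to 32 FPKM at P14. Of 7 erythroid genes none rose and 5 fell (6 adjusted over the list alone; 5 without P14 replicate 1), with a median of -1.48. The globin genes Hba-a1, Hbb-bs and Hbb-bt went from 959 ± 216 to 160 ± 42.9, from 872 ± 133 to 204 ± 41.7 and from 128 ± 17.3 to 29.1 ± 10.1 FPKM, and each is uncertain because near-identical copies lie beside it. The erythroid list passed camera at adjusted p = 0.000737 (adjusted p = 0.22 with an estimated correlation).

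Lists of epithelial genes were higher at P14. The epithelial level given above is made from the pan-epithelial markers, so that list follows it by construction. Of 16 pan-epithelial markers 12 rose and none fell (15 up adjusted over the list alone; 14 without P14 replicate 1), with a median of 3.39 (camera adjusted p = 1.46e-06; adjusted p = 0.52 with an estimated correlation). Cdhr2, a cadherin of the brush border, was at 659 FPKM in P14 replicate 1 and 2.87 to 47.6 in the other P14 libraries, against 0.0253 ± 0.0277 at E17.5, a call lost without any one E17.5 library or P14 replicate 3 (adjusted p 0.0686 to 0.0775). Of 21 enterocyte genes 8 rose and none fell (12 up adjusted over the list alone; 13 up and 1 down without P14 replicate 1; camera adjusted p = 1.37e-05; adjusted p = 0.52 with an estimated correlation). Among 9 secretory and stem cell genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; 8 and 1 without P14 replicate 1; camera adjusted p = 0.00412; adjusted p = 0.22 with an estimated correlation). After subtraction of the epithelial share, the pan-epithelial (camera adjusted p = 0.915) and enterocyte (0.558) lists did not pass. The secretory list did (0.0314), although the log2 fold change of its member Tff3 turned to -0.629. The enterocyte direction turned with the epithelial level as a covariate (0.946). Both settings were added after the data had been seen. Olfm4, a stem cell marker, was at 2.17 to 85.5 FPKM at P14 and 0.43 ± 0.204 at E17.5 (adjusted p = 0.0543 without E17.5 replicate 3). Tff3, a goblet cell peptide, was at 4.31 to 330 FPKM at P14 and 0.552 ± 0.152 at E17.5, a call lost without any one E17.5 library or P14 replicate 3 (adjusted p 0.103 to 0.11), and Agr2, a secretory chaperone, rose by 3.07 (SE 0.67). Smoc2, which fibroblasts also make, was at 65.9 ± 4.07 and 116 ± 50.9 FPKM, with 40.3 in P14 replicate 1 (adjusted p = 0.26, and 2.65e-05 without P14 replicate 1).

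Genes of mitochondrial respiration rose together. Of 60 nuclear-encoded oxidative phosphorylation genes 53 rose and none fell (57 up adjusted over the list alone; 57 without P14 replicate 1), with a median of 0.66 (camera adjusted p = 1.3e-24; adjusted p = 0.22 with an estimated correlation). Ndufs6 and Ndufa2, subunits of complex I, went from 22.6 ± 6.66 to 63.7 ± 12.4 and from 48.4 ± 16.3 to 123 ± 18.7 FPKM. Cox5b, a subunit of cytochrome oxidase, went from 67.71 ± 16.2 to 175 ± 16.1 FPKM, and Atp5b, of ATP synthase, rose by 0.49 (SE 0.1, adjusted p = 0.0112).

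The remaining lists are given as counts. Of 78 cytosolic ribosomal protein genes 3 rose and 19 fell (5 and 19 adjusted over the list alone; 6 and 31 without P14 replicate 1; median -0.23, camera adjusted p = 0.0133; adjusted p = 0.67 with an estimated correlation), a set call lost without E17.5 replicate 1 (adjusted p = 0.0694). Of 12 genes of MHC class I presentation 4 rose and none fell (5 up adjusted over the list alone; 5 without P14 replicate 1; median 0.68, camera adjusted p = 0.00354; adjusted p = 0.59 with an estimated correlation). Their mean level was 6.07 in P14 replicate 1 and 4.61 to 5.12 in the other P14 libraries. The set did not pass by fry (0.0678) or, in settings added after the data had been seen, with the epithelial share subtracted (0.097) or the epithelial level as a covariate (0.72, direction down). Of 10 class II genes none rose and 2 fell (also adjusted over the list alone; 3 without P14 replicate 1; camera adjusted p = 0.495, with the direction up without P14 replicate 2, 0.6). Of 8 adipocyte genes 5 rose and none fell (5 and 1 adjusted over the list alone; 5 and 2 without P14 replicate 1; median 0.78, camera adjusted p = 0.0454; adjusted p = 0.32 with an estimated correlation), a set call lost without P14 replicate 1 (0.12), E17.5 replicate 2 (0.0521) or E17.5 replicate 4 (0.0548). Of 6 mast cell genes 1 rose and 4 fell (also adjusted over the list alone and without P14 replicate 1; median -1.23, camera adjusted p = 0.0164; adjusted p = 0.32 with an estimated correlation), a set call lost without P14 replicate 1 (0.0941). Of 6 granulocyte genes 1 rose and 3 fell (1 and 4 adjusted over the list alone; 1 and 4 without P14 replicate 1; camera adjusted p = 0.0645, and 0.0403 without P14 replicate 3).

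Of 11 pericyte genes 1 rose and 4 fell (also adjusted over the list alone; 3 and 5 without P14 replicate 1; median -0.50, camera adjusted p = 0.0614), a set that passed without E17.5 replicate 3 (0.0494) or P14 replicate 2 (0.0202), 3 (0.0389) or 4 (0.0294), with a median of -0.16 and adjusted p = 0.414 without P14 replicate 1. Of 15 T, NK and innate lymphoid genes 1 fell, Gzma, and none rose (also adjusted over the list alone; 1 and 1 without P14 replicate 1; camera adjusted p = 0.871). Their median was 0.02 and the test direction up, while without P14 replicate 1 the median was 0.02, the mean -0.08 and the test direction down (0.985), as also without P14 replicate 4 (0.609). Of 24 interferon-stimulated genes 1 rose and 5 fell (also adjusted over the list alone; 4 and 9 without P14 replicate 1), with a median of 0.09, a mean of 0.19 and the test direction up (camera adjusted p = 0.983), which turned down without P14 replicate 1 (median -0.15, adjusted p = 0.509), E17.5 replicate 1 (0.721), E17.5 replicate 2 (0.955) or E17.5 replicate 4 (0.923), and passed downwards with the epithelial level as a covariate, added after the data had been seen (0.0392). That covariate did not overlap between the ages. Of 24 immediate early and heat shock genes 2 rose and 2 fell (also adjusted over the list alone; 3 and 6 without P14 replicate 1), with a median of 0.06 and the test direction up (camera adjusted p = 0.867). Their median without P14 replicate 1 was -0.08, their mean 0.05 and the test direction down (0.901), as also without P14 replicate 4 (0.952). Pancreatic acinar and skeletal muscle lists, included for neighbouring tissue, had 3 and 4 tested members, too few for the set test; 2 acinar genes were called up and 1 down, and 1 skeletal muscle gene up.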

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

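All tests of explanations and of other splits in this part were chosen after the results were seen. A sample was singled out when its gap to the nearest other library of its age exceeded 0.83 of the range of the 4. Chance flags about 1 in 20 groups. Of 344 groups of 4 values, 45 met the criterion where 17.2 would by chance, and in 32 of the 45 the library was P14 replicate 1.

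P14 replicate 1 was the lowest P14 library in the mean level of YAP and TAZ targets (gap 0.897 of the range), collagens (0.932), basement membrane (0.848), planar cell polarity (0.94), hedgehog response (0.833), mesothelium (0.858) and IGF and FGF genes (0.941). It was also the lowest P14 library for Cttnbp2nl (0.864), Map4k4 (0.882), Hnrnpa1 (0.875), Qk (0.907), Nova2 (0.951), Top2a (0.958), Lox (0.915), Fbn2 (0.852), Sparc (0.924), Lamb1 (0.909), Col4a1 (0.841), Fat4 (0.875), Ptk7 (0.913), C3 (0.876), Calb2 (0.841), Kit (0.862), Gpr20 (0.955), Col18a1 (0.852), Smoc2 (0.936), Upk3b (0.865), Igf1 (0.877) and Pdgfrb (0.852), and the highest for Mob1a (0.84), Entpd2 (0.906) and Igf2 (0.834).

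Other libraries stood apart for single results. P14 replicate 3 was high for Col6a5 (0.833) and Rps2 (0.901), and P14 replicate 2 high for Actc1 (0.853) and Hba-a1 (0.911) and low for Srpk3 (0.83). E17.5 replicate 1 was high in the levels of the smooth muscle list (0.831) and the lymphatic list (0.832) and low for Nt5e (0.835). E17.5 replicate 2 was high for Scg2 (0.872). E17.5 replicate 3 was high for Meltf (0.935) and Igha (1, the other 3 being listed at 0) and low for Krt7 (0.861) and Igf2 (0.83).

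The first pattern is P14 replicate 1 itself. Sequencing depth is argued against by its reads, 0.998 times the mean of the other P14 libraries, and the authors' effective library size by the pan-epithelial median log2 ratio, 3.87 as deposited and still 3.44 when scaled by assigned reads. Epithelial cells left in the preparation are a candidate explanation: all 9 lists of wall cell types had an upper quartile of the ratio to the other P14 libraries under 1, while all pan-epithelial markers were higher. The ratios were not alike, from 0.15 for mesothelium to 0.78 for lymphatics, and outside the 9 lists macrophages were at 0.74 (upper quartile 1.3), T and NK genes at 1.4 and B and plasma cell genes at 1.7, which dilution alone does not give, so a difference in which cells were sampled stays open. No biological explanation was tested, since all 4 P14 libraries carry the same labels.

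The second pattern is in 4 Y-linked genes, which were not tested, and in Xist, which was tested and not called (log2 fold change -2.9, limma adjusted p = 0.212). E17.5 replicate 2 held 3879 reads of Y-linked genes, where the other E17.5 libraries held 0 to 10 and a count of 0 allows 3, and it also held 5293 Xist reads. Its Xist level was 16.5% of the mean of the other E17.5 libraries and its Y-linked level 84.1% of that in P14 replicates 1 and 3, values consistent with tissue of male and female fetuses in 1 library. The Y-linked P14 libraries held at most 50 Xist reads, which argues against carry-over on that scale across all libraries. It does not cover carry-over from the other E17.5 libraries, which held 28526 to 42121 Xist reads, so that stays open. Sex was thus not balanced, with Y-linked reads in P14 replicates 1 and 3 (4375 and 4781) and few in P14 replicates 2 and 4 (21 and 7), and its effect was not tested.

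The third pattern is Rps2 and Hmgn2, whose FPKM differed many-fold between P14 libraries. For Rps2 the highest P14 library was 36.9 times the lowest in scaled reads, but 1.53 times once the reads of its 10 named copies were added, which may mean that reads moved between the gene and its copies. The yardstick, the 95th percentile over 77 other ribosomal protein genes (2.6, with a median of 1.2 and a highest value of 19), was chosen after a first bound of 2-fold on the unscaled sum had been missed at 2.05, so this test is weak. Hmgn2, at 66.9 and 71.9 FPKM in P14 replicates 1 and 3 and 8.18 and 7 in replicates 2 and 4, had no named copies to add, so its 10.1-fold range in reads cannot be told apart from a real difference. Its call (adjusted p = 0.0457) was lost without any one E17.5 library, P14 replicate 2 or P14 replicate 4 (0.0898 to 0.105).

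The counts were also made for other splits of the libraries. Of the 35 splits of the 8 libraries, 1, the real one, gave as many as 3473 genes, with 1 gene in the highest other split, and the same held for the 1007 genes with a 2-fold change (highest other 1). Without P14 replicate 1, 1 of 35 splits reached 6958 and 1187 genes (highest other 1 each). A share of 1 in 35 is the smallest these splits allow. Each other split mixes the ages, which widens the spread, so low counts there were built in and do not exclude chance. The splits also cannot tell age from other differences between the groups, such as the epithelial level. The number of lists called was not particular to the real split: 10 of 35 splits gave 24 lists or more, with 27 in the highest other, and 3 of 35 gave 23 without P14 replicate 1, with 23 in the highest other. Camera with a preset correlation thus called as many lists for some arbitrary splits of these libraries, and with an estimated correlation 1 list stayed called, and 0 without P14 replicate 1.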

How the results depend on the processing

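The alternatives named as added were chosen after the data had been seen; the others were planned. The cause of each change below was not tested, except that fewer genes or libraries enter some settings. Lists named here are given by the adjusted p of their set test and genes by their log2 fold change. With 1 library left out in turn, the genes called ranged from 1735 to 6958, those up from 617 to 3176, those down from 1118 to 3782, those changed 2-fold from 712 to 1187 (285 to 771 up, 416 to 535 down) and the lists called from 22 to 27. The spliceosome test ranged from 0.0167 to 0.0707, while the STRIPAK test never passed; the mean level difference of the spliceosome ranged from -0.124 to -0.0848 and that of STRIPAK from -0.0889 to -0.0286. Pseudocounts of 0.1 and 0.5, no trend or robust moderation and protein-coding genes alone left every gene count within 1.5 times the reported one. No gene filter gave 2578 of 31574 genes, and a mean FPKM of 5 or more gave 2372 of 9492, with 1398 down; there the mast cell and granulocyte lists had too few members for a value.

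Scaling moved directions. Rescaling to TPM gave 899 genes up and 2678 down, of which 498 and 931 changed by 2-fold or more. The spliceosome test missed the threshold after median-of-ratios scaling (0.0543), and array weights gave 7726 genes, 3530 up and 4196 down. Tests that turned direction were those of decay factors with no filter (0.927), a mean FPKM of 5 or more (0.899), TPM (0.695) and array weights (0.84). So did interferon-stimulated genes with no filter (0.357), median-of-ratios (0.962), array weights (0.348), fry (0.729) and voom (0.925, added), immediate early genes with no filter (0.927) and fry (0.9), and T and NK genes with protein-coding genes alone (0.838) and fry (0.505). Genes that turned were Snrpb (-0.00463 with TPM, -0.0113 with quantiles), Actg2 (-0.0502, -0.34), Lyz2 (-0.156, -0.166), Uchl1 (-0.0451 with TPM) and Sparc (0.0535 with array weights). None of these genes was called with all libraries. Voom gave 765 genes down by 2-fold or more.

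The estimated correlation left 1 list called, fetal growth genes, and 0 without P14 replicate 1 (added); the spliceosome test then gave 0.43. Fry called 23 lists. The smooth muscle (0.279), collagen (0.279) and MHC class I (0.0678) lists, which camera called, did not pass it.

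The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.033, 0.0095, -0.064 and -0.049. With the replicate block 1744 genes were called, 695 up and 1049 down, and 336 up by 2-fold or more. The paired difference in the spliceosome mean level was -0.105, reached by 2 of 16 exact sign flips, the fewest possible. The block ended no list call and added those of fibroblast niche signals and granulocytes.

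The added settings aimed at the epithelial level. With the epithelial share subtracted and P14 replicate 1 left out, 6953 genes were called, 2708 up and 4245 down, and the spliceosome test gave 0.1. Of the lists called with all libraries, those of collagens (0.915), basement membrane (0.246), hedgehog response (0.154), IGF and FGF genes (0.758), mast cells (0.169), adipocytes (0.1), MHC class I (0.097), ribosomal proteins (0.0663), pan-epithelial markers (0.915) and enterocytes (0.558) did not pass there either. The tests of tissue-restricted regulators (0.601), decay factors (0.987), planar cell polarity (0.742), niche signals (0.758), T and NK genes (0.915), interferon-stimulated genes (0.153) and immediate early genes (0.805) turned, as did Guca2a (-0.468), Clca4b (-0.0436), Folr1 (-0.297), Meltf (-0.151), Alpi (-0.0924), Cdhr5 (-0.203), Spink1 (-0.359), Naaladl1 (-0.862), Epcam (-1.07), Cdhr2 (-0.0357), Tff3 (-0.629), Sparc (0.123) and Lyz2 (-0.205). Subtraction takes off transcripts in proportion to the P14 replicate 1 profile, by a share set from the pan-epithelial markers. The lost call of the pan-epithelial list and the falls of epithelial genes were thus largely built in. The list of secretory epithelial and stem cell genes stayed called after the subtraction (median 0.94, 5 up and 2 down, 0.0314). Its goblet cell member Tff3 turned, and it holds Smoc2, which fibroblasts also make. The call therefore does not show a rise of secretory epithelium.

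With P14 replicates 1 and 3 left out (added), 6184 genes were called, 2910 up and 3274 down; the spliceosome test gave 0.0665 and its mean level -0.108 (exact p = 0.133). Tissue-restricted regulators (0.622), decay factors (0.826), T and NK genes (0.875), interferon-stimulated genes (0.339) and immediate early genes (0.69) turned, as did Sparc (0.0956), Lyz2 (-0.4) and Xist (0.0898).

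With the epithelial level as a covariate (added), 2226 genes were up, and 2071 changed by 2-fold or more, 1152 up and 919 down; the spliceosome test gave 0.263. Collagens (0.00445), planar cell polarity (0.0482), tissue-restricted regulators (0.0392) and interferon-stimulated genes (0.0392) turned and passed the threshold in the new direction. YAP and TAZ targets (0.72), SR proteins (0.791), decay factors (0.804), basement membrane (0.828), hedgehog response (0.907), niche signals (0.72), pericytes (0.213), T and NK genes (0.282), enterocytes (0.946), MHC class I (0.72), immediate early genes (0.694) and IGF and FGF genes (0.72) also turned. Of the 24 lists called with all libraries, 7 stayed called in the same direction: mitosis, smooth muscle, fetal growth, macrophages, erythroid genes, ribosomal proteins and oxidative phosphorylation. Genes that turned were Sparc (0.671), Col4a1 (0.266), Lyz2 (-0.898), Tff3 (-0.388) and Xist (1.69). The covariate did not overlap between the ages, so the changes of direction under it rest on extrapolation.

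Leaving out 1 library turned the direction of some results, given here with their whole range: interferon-stimulated genes (0.509 to 0.996), T and NK genes (0.127 to 0.985), immediate early genes (0.559 to 0.955), MHC class II (0.271 to 0.6), decay factors (0.609 to 0.98), tissue-restricted regulators (0.0692 to 0.98), Lyz2 (-0.154 to 0.387), Actg2 (-0.084 to 0.584), Uchl1 (-0.0861 to 0.633) and Sparc (-0.377 to 0.0749). Over all settings, the spliceosome test no longer passed in 8, and the STRIPAK test changed in none. Of the tests of the other 39 lists, 803 kept direction and side of the threshold, 46 passed it newly, 72 no longer passed and 52 turned; for the named genes the numbers were 2678, 79, 206 and 38. Depth was alike across libraries, so it limits mainly genes with few reads.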

Other observations

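No explanation was tested in this part, and what it describes was chosen after the values were seen. Without P14 replicate 1, the median log2 change was 0.97 for smooth muscle, 1.01 for mesothelium, 0.60 for enteric neurons and 0.63 for Cajal cell genes, while it was -0.67 for blood and -0.89 for lymphatic endothelium. With all libraries the mesothelium, neuron and Cajal cell lists did not pass camera (adjusted p = 0.088, 0.0853 and 0.32). Whether these medians differ from each other was not tested, and shares of cells cannot be told from levels per cell in bulk RNA.

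Within the glia list Ednrb went against the other called members: it fell by 2.64 on the log2 scale (SE 0.187, adjusted p = 0.000369 by limma) while Entpd2 and Scn7a rose by 1.84 and 1.5. Adamdec1 and Hmgn2 divided the P14 libraries in the same way, with 425 and 496 FPKM of Adamdec1 and 66.9 and 71.9 of Hmgn2 in replicates 1 and 3, and 95 and 110 of Adamdec1 and 8.18 and 7 of Hmgn2 in replicates 2 and 4. Replicates 1 and 3 are also those with Y-linked reads (4375 and 4781) and the higher epithelial levels (100% and 14%). Across all libraries neither gene rose steadily with the epithelial level. Both were higher in replicate 3 than in replicate 1 and higher still in the E17.5 libraries, where that level was at most 0.454%. This does not exclude a link with the epithelial level within P14. The cause of the division was not tested.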
